A study of Mus musculus with 17 samples.

How the data were processed

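RNA was sequenced from E11 cells, a mouse podocyte line, grown on silicone (PDMS) substrates with 3 surfaces. The labels give NT as the surface without topography (5 libraries), RT as round topography that is not fractal (6 libraries) and HF as high fractal topography taken from tracings of healthy glomerular histology (6 libraries). Per the labels, poly-A RNA was selected, the libraries were non-directional, and they were read in pairs (2 x 150 bases). What separates one replicate from another, such as culture, passage or substrate, is not stated. Replicate numbers 1 to 5 occur in all groups and number 6 in RT and HF.

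The deposited file holds raw counts per gene and library, with no normalization. The authors' processing notes name CASAVA without a version, HISAT2 2.0.5, featureCounts 1.5.0-p3 and the mouse build GRCm39, without saying what each did. The annotation release, the strand setting and any filter are not stated, so genes that overlap others on either strand carry that limit here. The table held 56748 genes by Ensembl gene identifier, all values were whole numbers, and every column was used. Gene symbols, transcript sequences and overlaps came from GENCODE M21, which is built on the earlier assembly GRCm38, so no position is given. Of the identifiers, 52073 had a symbol there, and those without one held 0.580% of the counts.

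Total counts per library ran from 14.9 to 24.1 M. With this depth and number of libraries, data simulated from these counts with 200 changed genes were tested. At 2-fold changes the test recovered 88% of the genes for HF against NT, 86% for HF against RT and 88% for RT against NT, at 1.5-fold changes 66%, 76% and 68%, at 1.25-fold changes 50%, 62% and 54%, and at 1.15-fold changes 32%, 36% and 32%. The median fold among the genes called in the deposited counts was 1.18, 1.21 and 1.19. It called 10, 5 and 5 unchanged genes. The p-values measure the spread between these libraries, which may be technical, and what they say about other cultures depends on what the replicates are.

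Genes were kept by filterByExpr on the groups, which left 15196, of which 14933 had a symbol. Counts were scaled by TMM and fitted with edgeR 4.0.16 by the quasi-likelihood F test with robust estimation, with 1 mean for each of the 3 groups in 1 fit and no covariate. The common biological coefficient of variation was 0.0603. The p-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The comparisons were HF against NT, HF against RT and RT against NT, each as the first group minus the second. Standard errors of log2 fold changes are the fold change divided by the square root of F. CPM use the TMM-scaled totals and are given as mean ± SD.

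The gene lists, 33 in number, were written before the data were examined, as were the tests, the comparisons, the alternatives and the rule for named genes, except where the text says otherwise. Of these lists, 31 had at least 5 tested members. They were tested with limma 3.58.1 by camera on voom values with a preset correlation of 0.01, which asks whether the members moved relative to the other genes, and adjusted by Benjamini-Hochberg over the 31 lists. Beside it stand camera with an estimated correlation and fry. Several genes are members of more than 1 list. For each list the number of members past the threshold is given after adjustment over all genes tested and when adjusted over the list alone.

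The rule for named genes took, in each comparison, genes past the threshold with an average log2 CPM of at least 1 and an ordinary gene name. Among these it took the 8 largest rises and the 8 largest falls. Besides these it took up to 4 members with the smallest p of each list described, and the podocyte genes Nphs1, Synpo, Wt1 and Podxl were always given. Not every gene the rule took is named in the text. Other genes named were chosen after their values were seen, and the text says so. For each named gene, the share of 100-base windows of its longest transcript that also occur in transcripts of another gene was counted.

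The separation of the libraries of 2 groups was the share of the sum of squares of log2 CPM (prior count 2) between groups over the 1000 most variable tested genes, with an exact one-sided permutation test over all splits. Total counts, genes detected, the share of the 10 largest genes and the share of mitochondrially encoded counts were compared by exact two-sided permutation tests, adjusted over the 12 tests. The overlap of HF against NT with RT against NT, which share the NT libraries, was set against 20 simulated sets of unchanged groups. In these all libraries were simulated, NT included, and both comparisons used the same simulated NT libraries. Each gene was drawn independently, so the simulation holds no correlation between genes. The overlap was also set against the 20 ways of dividing the deposited NT libraries between the comparisons. The counts of changed genes were also recomputed for 100 random splits of the libraries of each comparison, the real one included.

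The alternatives were DESeq2 size factors and upper-quartile scaling in edgeR, no filter beyond 1 count, a stricter filter (10 counts in at least 5 libraries and an average log2 CPM of at least 1), the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, no robust estimation, only the 2 groups compared in the fit, the replicate number as a block, an added threshold of 1 on the log2 fold change, 500 or all genes and a prior count of 0.5 in the separation test, and each library left out in turn. Fits on the libraries numbered 1 to 5, on counts thinned to the smallest library total, and camera with both an estimated correlation and the block were chosen after seeing the data. Computation used R 4.3.3, the R package data.table (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9.

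Libraries were checked for duplicates by the counting error between pairs, and none was found. The replicate numbers were not used as pairs, since the labels give them no meaning. The lists with fewer than 5 tested members were not tested as lists.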

Results

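Gene expression was measured in 17 libraries of E11 mouse podocytes, the epithelial cells whose interdigitating foot processes cover the glomerular capillaries, on flat silicone (NT, n = 5), on a round topography that is not fractal (RT, n = 6) and on a highly fractal topography (HF, n = 6). The series title names podocyte maturation on fractal topography as its subject, and the labels give NT and RT as the controls of HF. Total counts averaged 16.7 ± 1.37 M in NT (SD, n = 5), 19.2 ± 3.40 M in RT (SD, n = 6) and 17.1 ± 0.547 M in HF (SD, n = 6). Among 12 exact permutation tests of depth and composition between pairs of groups, the smallest p was 0.0455, for the genes detected in RT (22497 on average) against NT (22043), with an adjusted p of 0.344.

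On the flat surface the cells held Synpo (synaptopodin, an actin-associated podocyte protein) at 282 ± 24.7 CPM, Podxl (podocalyxin, the main sialoprotein of the podocyte surface) at 131 ± 8.30 CPM and Wt1 (a transcription factor of podocytes) at 115 ± 3.02 CPM (SD, n = 5). Nphs1 (nephrin, the slit diaphragm protein) stood at 3.96 ± 0.788 CPM (SD, n = 5). Genes known from kidney tubules were abundant in the same libraries, with Cdh16 at 977 ± 37.8 CPM and Lrp2 at 382 ± 76.3 CPM (SD, n = 5). These were chosen after their values were seen.

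**Figure D1:**
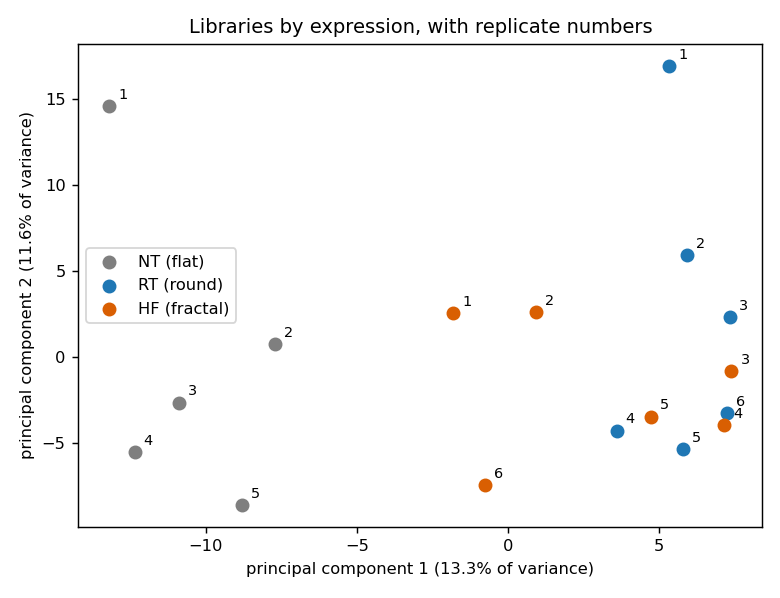
Principal components of log2 CPM over the most variable tested genes, 1 point per library colored by group, with PC1 on the x axis (13.3% of the variance) and PC2 on the y axis (11.6%). The 5 NT libraries lie between -13.2 and -7.69 on PC1 and the 6 RT libraries between 3.60 and 7.35, with the HF libraries from -1.81 to 7.40. PC2 tends to fall with the replicate number in each group, though not at each step.

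The comparison of HF with NT asks what cells on the fractal surface express differently from cells on a flat one. On HF, the SRF and MRTF targets and a small list of mesangial, pericyte and smooth muscle markers were higher as groups with the preset and with an estimated correlation. With the preset correlation alone, lists of actin, glomerular and fibrillar matrix, cell division and immediate early genes were also higher and interferon-response genes lower. Slc6a18, a neutral amino acid transporter of the proximal tubule, rose by a log2 fold change of 3.07 ± 0.56 (SE), from 0.907 ± 0.586 CPM (SD, n = 5) to 7.47 ± 4.33 CPM (SD, n = 6, adjusted p = 0.00967). Havcr1 (kidney injury molecule 1) rose by 2.44 ± 0.31 on the log2 scale, from 3.72 ± 1.07 CPM (SD, n = 5) to 19.9 ± 6.32 CPM (SD, n = 6, adjusted p = 0.000618). For both genes, all 6 HF libraries lay above all 5 NT libraries.

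Across 15196 genes tested, 354 changed, of which 228 rose and 126 fell. Changes were small, with a median absolute log2 fold change of 0.24 among them, and 23 were at least 2-fold (20 up, 3 down). Among genes with an average log2 CPM of at least 1, the largest rises besides Slc6a18 and Havcr1 were Cyp2j5 (a cytochrome P450 of kidney), Msln (mesothelin, a surface protein), Tspan8 (a tetraspanin), Atg9b (an autophagy protein), Cckar (a cholecystokinin receptor) and Ppbp (a platelet chemokine), between 1.28 and 1.60 on the log2 scale. The call of Ppbp ended without NT 2, NT 3 or NT 4 (adjusted p = 0.0547, 0.0677 and 0.0565) and with only the 2 groups in the fit (adjusted p = 0.0743). The tubular epithelial markers fixed in advance had 0 of 8 tested members past the threshold by edgeR (2 rose when adjusted over the list alone). As a list they were higher than other genes (camera adjusted p = 0.0226, and adjusted p = 0.293 with an estimated correlation), a call that ended without NT 3, NT 5, HF 2 or HF 3 (adjusted p = 0.0620, 0.219, 0.0617 and 0.0632). Falls were smaller. Folh1 (glutamate carboxypeptidase II) had a log2 fold change of -0.59 ± 0.10 (SE, adjusted p = 0.000706), with all 6 HF libraries below all 5 NT libraries. Ndst3, a heparan sulfate sulfotransferase, had -0.49 ± 0.09 (SE, adjusted p = 0.00209). Tgtp1, an interferon-induced GTPase, had -0.53 ± 0.06 (SE, adjusted p = 6.34e-06), but 83.2% of its sequence windows also occur in another gene.

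**Figure D2:**
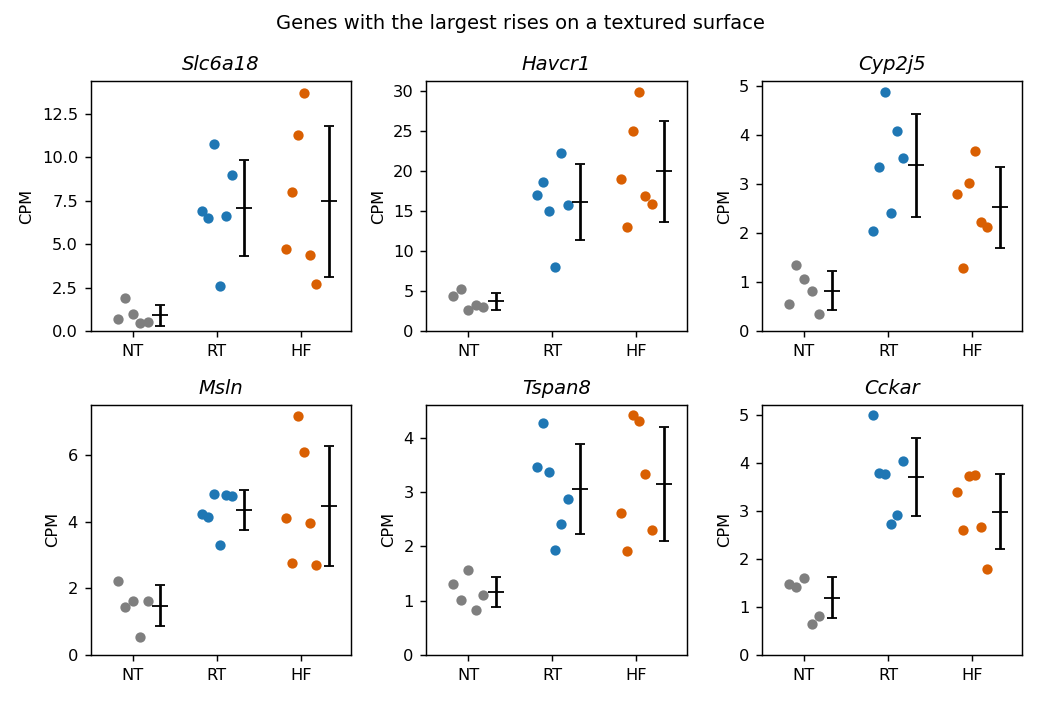
CPM of Slc6a18, Havcr1, Cyp2j5, Msln, Tspan8 and Cckar on a linear axis, 1 point per library, by group (NT, RT, HF), with bars for the mean and SD of each group. Havcr1 lies between 2.63 and 5.21 CPM in the 5 NT libraries, between 7.96 and 22.2 in RT and between 12.96 and 29.8 in HF.

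Podocyte genes did not move as a group (camera adjusted p = 0.534). Of 34 tested members of the podocyte slit diaphragm and identity list, 1 rose, 2 fell and 31 did not pass (4 rose and 3 fell when adjusted over the list alone). Wt1 fell, with a log2 fold change of -0.16 ± 0.04 (SE), from 115 ± 3.02 CPM (SD, n = 5) to 103 ± 5.22 CPM (SD, n = 6, adjusted p = 0.0113). Pdpn (podoplanin, a sialoglycoprotein of foot processes) fell to 153 ± 4.51 CPM (SD, n = 6) from 175 ± 5.97 CPM (SD, n = 5), a log2 fold change of -0.19 ± 0.03 (SE, adjusted p = 0.000972), with all 6 HF libraries below all 5 NT libraries. Actn4 (alpha-actinin 4, an actin crosslinker of foot processes) rose by 0.13 ± 0.03 on the log2 scale (SE, adjusted p = 0.0285), a call that ended without NT 3, NT 4, HF 1, HF 3 or HF 4 (adjusted p = 0.0928, 0.0699, 0.0850, 0.0740 and 0.0850). Nphs1 had a log2 fold change of 0.35 ± 0.15 (SE, adjusted p = 0.270), Podxl -0.05 ± 0.04 (SE, adjusted p = 0.695) and Synpo -0.10 ± 0.04 (SE, adjusted p = 0.20), which did not pass. Without NT 1, the Synpo fold change was -0.15 and passed (adjusted p = 0.00767). Nes (nestin, an intermediate filament protein of podocytes) had 0.19 ± 0.05 (SE, adjusted p = 0.0506), and passed with DESeq2 and limma voom among 10 alternative settings (lowest adjusted p 8.26e-05).

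**Figure D3:**
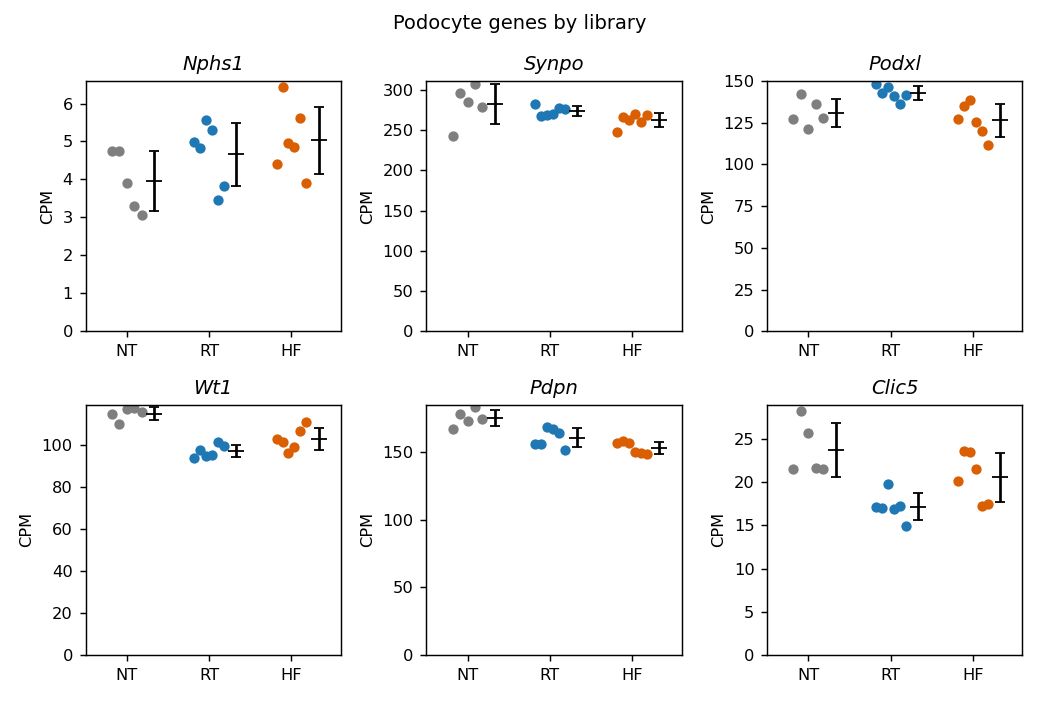
CPM of Nphs1, Synpo, Podxl, Wt1, Pdpn and Clic5, 1 point per library, by group (NT, RT, HF), with bars for the mean and SD of each group. Wt1 lies between 110 and 117 CPM in the 5 NT libraries, between 93.8 and 101 in RT and between 96.1 and 111 in HF, and Nphs1 between 3.07 and 6.42 over all 17 libraries.

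Of the contractile and mechanical lists, some were higher on HF and others did not pass. Of the SRF and MRTF targets, 4 of 26 rose and 0 fell (5 and 0 when adjusted over the list alone). The list passed with the preset and with an estimated correlation (camera adjusted p = 3.70e-09 and 0.0386). As written it includes Fos, Fosb, Egr1, Egr2 and Ier2, which also stand in the immediate early list, so it does not read actin dynamics alone. Acta2 (smooth muscle actin) rose by 0.48 ± 0.10 on the log2 scale (SE), from 261 ± 36.7 CPM (SD, n = 5) to 364 ± 42.2 CPM (SD, n = 6, adjusted p = 0.0171), a call that ended with only the 2 groups in the fit (adjusted p = 0.0749). It was also the 1 of 7 mesangial, pericyte and smooth muscle markers that rose, a list that passed both ways (camera adjusted p = 0.00109, and 0.0423 with an estimated correlation). The actin and actomyosin list had 4 of 50 members up, Flnc (filamin C) by 0.17 ± 0.04 on the log2 scale (SE, adjusted p = 0.00768), and none down (8 and 1 when adjusted over the list alone), with a camera adjusted p of 0.00181 (adjusted p = 0.160 with an estimated correlation). YAP and TAZ targets, read out as mechanical signalling, had 4 of 24 up and 0 down (7 and 0 when adjusted over the list alone). Camera gave an adjusted p of 4.80e-05, and an adjusted p of 0.125 with an estimated correlation. Among them Ccdc80, a matrix protein, rose by 0.24 ± 0.05 (SE, adjusted p = 0.00927). Of 37 focal adhesion and integrin genes, 5 rose and 1 fell (8 and 2 when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.184). Nor did mechanosensitive channels and nuclear lamina, of which 1 of 20 rose (camera adjusted p = 0.152). The focal adhesion gene that fell was Cav1 (caveolin 1), with a log2 fold change of -0.18 ± 0.03 (SE, adjusted p = 0.00120).

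Matrix genes were higher on HF as lists, with the preset correlation only. In the glomerular basement membrane list 2 of 21 rose and 0 fell (7 and 1 when adjusted over the list alone). As a list they had a camera adjusted p of 9.26e-08, and an adjusted p of 0.130 with an estimated correlation. Hspg2 (perlecan) rose by 0.23 ± 0.05 on the log2 scale (SE), from 921 ± 74.6 CPM (SD, n = 5) to 1083 ± 63.9 CPM (SD, n = 6, adjusted p = 0.00435). The other was Lama5 (a laminin chain of the mature membrane), at 0.24 ± 0.05 (SE, adjusted p = 0.0164), which did not pass without NT 3 or NT 5 (adjusted p = 0.0564 and 0.0722). Of the fibrillar matrix list 6 of 34 rose and 0 fell (11 and 4 when adjusted over the list alone). The camera test gave an adjusted p of 1.01e-05, with an adjusted p of 0.130 under an estimated correlation. Col8a1 (a short-chain collagen) rose by 0.35 ± 0.05 (SE, adjusted p = 0.000130) and Loxl1 (an elastin crosslinking oxidase) by 0.17 ± 0.03 (SE, adjusted p = 0.00303), each in all 6 HF libraries above all 5 NT libraries.

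Immediate early and cell cycle genes were higher on HF as groups, with the preset correlation only. Of the immediate early genes, the first transcripts after a growth or stress signal, 5 of 27 rose and 0 fell (11 and 0 when adjusted over the list alone). By camera the list had an adjusted p of 5.87e-12, and an adjusted p of 0.108 with an estimated correlation. Dusp6, a phosphatase that restrains ERK, rose by 0.79 ± 0.10 on the log2 scale (SE), from 21.2 ± 2.75 CPM (SD, n = 5) to 36.8 ± 6.01 CPM (SD, n = 6, adjusted p = 0.000360), and Myc by 0.41 ± 0.08 (SE, adjusted p = 0.00196). This list also differed between replicate numbers, which took 93.6% of its variance within groups (permutation p = 0.000520). NT has no number 6, and with the libraries numbered 1 to 5, a setting chosen after seeing the data, the camera adjusted p was 1.07e-10. Cell division genes had 33 of 34 positive fold changes, 3 of which passed as rises (7 when adjusted over the list alone). Camera gave an adjusted p of 5.14e-10, and an adjusted p of 0.235 with an estimated correlation. DNA replication genes had 4 of 38 up and 0 down (8 and 1 when adjusted over the list alone, camera adjusted p = 1.79e-05, and adjusted p = 0.235 with an estimated correlation). Uhrf1, a factor that keeps DNA methylation through replication, rose by 0.35 ± 0.07 on the log2 scale (SE, adjusted p = 0.00316).

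Interferon-response genes were lower on HF, with negative fold changes in 32 of 35 and a median of -0.22 on the log2 scale (camera adjusted p = 5.40e-11, and adjusted p = 0.193 with an estimated correlation). After adjustment over all genes 2 fell by edgeR (17 when adjusted over the list alone), 9 by DESeq2 and 4 by limma voom, and 0 rose. Those by edgeR were Zbp1 (a sensor of left-handed nucleic acids), at -0.65 ± 0.16 (SE, adjusted p = 0.0201), and Usp18 (which removes ISG15), at -0.57 ± 0.14 (SE, adjusted p = 0.0218). Zbp1 did not pass without NT 5 or HF 4 (adjusted p = 0.0769 and 0.0623), nor Usp18 without HF 3 or HF 4 (adjusted p = 0.0513 and 0.0652). Without NT 5, its highest library, Usp18 passed with a smaller log2 fold change of -0.37. Inflammatory cytokines and NF-kB targets were higher (camera adjusted p = 0.00927, and adjusted p = 0.235 with an estimated correlation), with Ccl7, a monocyte chemokine, as the 1 of 24 that rose (4 when adjusted over the list alone), by 0.59 ± 0.09 (SE, adjusted p = 0.000125). That list call ended without NT 5, HF 1 or HF 6 (adjusted p = 0.104, 0.0591 and 0.0880). Of 6 immune markers only H2-Aa passed, as a fall that was lost when any of 9 single libraries was left out, and the list did not (camera adjusted p = 0.311). Of 10 parietal epithelial markers only Ncam1, an adhesion molecule, passed, with a log2 fold change of -0.23 ± 0.03 (SE, adjusted p = 2.53e-05), and the list did not (camera adjusted p = 0.489).

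Cytosolic ribosomal protein genes were slightly higher on HF, with positive fold changes in 68 of 79 and a median of 0.08 on the log2 scale (camera adjusted p = 4.70e-10, and adjusted p = 0.321 with an estimated correlation). Of these 3 rose and 1 fell by edgeR (4 and 1 when adjusted over the list alone), and 21 rose and 1 fell by limma voom. Mitochondrially encoded genes were lower in 12 of 12, with 1 past the threshold (3 when adjusted over the list alone). As a list they had a camera adjusted p of 9.08e-06, and an adjusted p of 0.130 with an estimated correlation. The 1 gene was mt-Nd6, a subunit of respiratory complex I, at -0.22 ± 0.04 (SE, adjusted p = 0.000484). It overlaps mt-Nd5 in 2.70% of its exonic bases, and in non-directional libraries its reads cannot be told from those of the opposite strand. Other lists were higher, cell cycle inhibitors and p53 targets (camera adjusted p = 0.00373), microtubules and cell processes (0.00803) and autophagy and lysosome (0.000462), each with an adjusted p of 0.130 with an estimated correlation. In all, 17 of 31 lists passed, 15 up and 2 down, and 2 with an estimated correlation.

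The libraries of HF and NT stood apart as a whole, with 15.9% of the variation between the groups (exact permutation p = 0.00216, the smallest that 462 splits can give). The count of 354 changed genes was 202 without NT 3, 203 without HF 4 and 604 without NT 5. It was 556 with DESeq2 and 200 with only the 2 groups in the fit, and with limma voom Slc6a18 did not pass (adjusted p = 0.128).

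The comparison of HF with RT asks what the fractal form adds to a topography that is not fractal. The number of genes that differed, 32 by edgeR, depended on the method. Actn3 (alpha-actinin 3, an actin crosslinker of fast muscle) was higher on HF, at 4.30 ± 0.565 CPM against 2.12 ± 0.579 CPM (SD, n = 6 each, log2 fold change 1.00 ± 0.19, SE, adjusted p = 0.00855). Agt (angiotensinogen, the precursor of angiotensin) was higher at 81.6 ± 7.60 CPM against 60.2 ± 4.95 CPM (SD, n = 6 each, log2 fold change 0.44 ± 0.06, SE, adjusted p = 0.000651). Cbs (cystathionine beta-synthase, of sulfur amino acid metabolism) was lower at 17.7 ± 1.83 CPM against 25.4 ± 2.92 CPM (SD, n = 6 each, log2 fold change -0.52 ± 0.08, SE, adjusted p = 0.000621). For each of the 3 genes, all 6 HF libraries lay beyond all 6 RT libraries.

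Of 15196 genes, 32 changed, with 20 higher and 12 lower on HF, and 1 of them was at least 2-fold. That was Dio2, a deiodinase of low expression chosen after its values were seen (log2 fold change 1.64, adjusted p = 0.000621). DESeq2 called 89 genes (44 higher, 45 lower), limma voom 84 (41 and 43), the fit with only the 2 groups 113 (52 and 61) and no filter beyond 1 count 148 (73 and 75). Other rises were Gda (guanine deaminase) at 0.76 ± 0.14 (log2, SE, adjusted p = 0.00855), St3gal1 (a sialyltransferase) at 0.36 ± 0.06 (SE, adjusted p = 0.0107) and Spp1 (osteopontin) at 0.54 ± 0.09 (SE, adjusted p = 0.0252). Spp1 stood at 2573 ± 320 CPM on HF and 1776 ± 142 CPM on RT (SD, n = 6 each), and 18.8% of its exons overlap another gene. Other falls were Adamtsl4 (a fibrillin-binding protein) at -0.18 ± 0.03 (SE, adjusted p = 0.00656), Jag1 (a Notch ligand) at -0.19 ± 0.04 (SE, adjusted p = 0.0252), Hes1 (a Notch target) at -0.27 ± 0.06 (SE, adjusted p = 0.0420) and Kitl (the ligand of the receptor Kit) at -0.43 ± 0.09 (SE, adjusted p = 0.0252). When single libraries were left out, the call of Spp1 was lost in 8 of 12 cases, of Jag1 in 8, of Hes1 in 10 and of Kitl in 6, while Actn3, Agt, Gda, St3gal1, Cbs and Adamtsl4 kept theirs in all.

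None of the 34 podocyte genes tested passed by edgeR between HF and RT (0 rose and 0 fell; 2 rose and 1 fell when adjusted over the list alone), where 9 had an unadjusted p under 0.05. DESeq2 and limma voom each called 1 rise and 1 fall. The list did not move (camera adjusted p = 0.850). Podxl stood at 126 ± 9.80 CPM against 143 ± 4.16 CPM (SD, n = 6 each), a log2 fold change of -0.17 ± 0.04 (SE, adjusted p = 0.0807). It passed with DESeq2 (adjusted p = 0.0392), limma voom (adjusted p = 0.0261), only the 2 groups in the fit (adjusted p = 0.0311) and no filter beyond 1 count, and without HF 3 (adjusted p = 0.0102). Nphs1 (0.12, adjusted p = 0.911), Wt1 (0.08, adjusted p = 0.506) and Synpo (-0.06, adjusted p = 0.760) did not pass.

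Of 31 lists, 8 passed by camera between HF and RT and none with an estimated correlation, where the adjusted p was 0.686 for ribosomal proteins, 0.342 for parietal epithelial markers and 0.676 for the other 6. Glomerular basement membrane genes (camera adjusted p = 0.00617, 0 of 21 passed by edgeR), fibrillar matrix genes (0.00658, 0 of 34) and actin and actomyosin genes (0.0374, 0 of 50) were lower on HF as lists. So were cholesterol synthesis and SREBP targets (0.010, 0 of 29) and the nuclear genes of oxidative phosphorylation (0.00423, 0 of 56). DNA replication genes (0.0124, 0 of 38) and cytosolic ribosomal proteins (0.00178, 1 of 79, as a fall) were higher as lists. At an unadjusted p under 0.05, the lists without a passing gene had 5, 7, 3, 2, 7 and 1 such members in the order given. DESeq2 called 1 fall among the actin genes and no other member of these lists, and limma voom none. Of 10 parietal epithelial markers 2 fell (3 when adjusted over the list alone, camera adjusted p = 0.0174). They were Ncam1, at -0.15 ± 0.03 (SE, adjusted p = 0.0109), and Cdh6, a cadherin, at -0.16 ± 0.04 (SE, adjusted p = 0.0474), the latter lost when any of 9 single libraries was left out. No list call held under all leave-outs, and the number of lists passing was 4 without RT 6 and 5 without HF 6. Immediate early genes (camera adjusted p = 0.560), interferon-response genes (0.612), YAP and TAZ targets (0.229) and SRF and MRTF targets (0.0722) did not pass, though DESeq2 and limma voom each called 2 falls among the last.

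The HF and RT libraries did not separate as a whole at the 0.05 threshold, with 10.6% of the variation between the groups (exact permutation p = 0.0541 over 924 splits), but did without RT 4, RT 5, RT 6 or HF 5 (exact permutation p = 0.0238, 0.0390, 0.0476 and 0.0476). The count of 32 genes was 14 without RT 1 or RT 3, 16 without HF 5, 18 without RT 2, HF 1, HF 4 or HF 6, and 89 without HF 3. At an unadjusted p under 0.05 there were 1216 genes.

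The comparison of RT with NT asks what a topography that is not fractal changes against a flat surface. It gave the largest count of changed genes of the 3 comparisons, with Slc6a18, Havcr1 and Cyp2j5 again among the largest rises. Actin and matrix genes were higher as groups with the preset correlation, and close to the threshold with an estimated one. Immediate early genes were higher and interferon-response genes lower with the preset correlation, and neither list passed with an estimated one. The immediate early list did pass with an estimated correlation and the replicate block together, a setting chosen after seeing the data. Whether these groups moved more than on HF is what the comparison of HF with RT tested. Kif12, a kinesin expressed in kidney epithelium, rose by 1.45 ± 0.16 on the log2 scale (SE), from 4.40 ± 1.02 CPM (SD, n = 5) to 12.03 ± 2.44 CPM (SD, n = 6, adjusted p = 8.85e-06). Wt1 fell, with a log2 fold change of -0.24 ± 0.04 (SE), from 115 ± 3.02 CPM (SD, n = 5) to 96.9 ± 2.96 CPM (SD, n = 6, adjusted p = 6.16e-05), and all 6 RT libraries lay below all 5 NT libraries.

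Of 15196 genes, 603 changed, with 384 up and 219 down, a median absolute log2 fold change of 0.25 and 55 at least 2-fold (50 up, 5 down). Slc6a18 rose by 2.99 ± 0.56 (log2, SE, adjusted p = 0.00718; adjusted p = 0.115 with limma voom), Havcr1 by 2.13 ± 0.31 (SE, adjusted p = 0.00119) and Cyp2j5 by 2.04 ± 0.29 (SE, adjusted p = 8.79e-05), each with all 6 RT libraries above all 5 NT libraries. The next largest rises among genes with an average log2 CPM of at least 1 were Cckar, Msln, Clca3a2 and Atg9b, at 1.46 to 1.62 on the log2 scale. Of 8 tubular epithelial markers 2 rose (2 when adjusted over the list alone, camera adjusted p = 0.0202, and adjusted p = 0.260 with an estimated correlation), a call that ended without NT 5 (adjusted p = 0.175). Of these, Hnf4a (a proximal tubule factor) rose from 0.299 ± 0.207 CPM (SD, n = 5) to 0.823 ± 0.323 CPM (SD, n = 6, adjusted p = 0.0252), a call lost when any of 4 single libraries was left out. By the same limit, the largest falls included H2-Aa (a class II MHC chain), with a log2 fold change of -0.98 ± 0.14 (SE), from 21.3 ± 5.02 CPM (SD, n = 5) to 10.7 ± 1.53 CPM (SD, n = 6, adjusted p = 0.000424), and Serpina3n (an acute-phase protease inhibitor), at -0.76 ± 0.16 (SE, adjusted p = 0.00326). Among the others, mt-Nd3, Amd2 and a second annotated entry of Myl12b share 96.0%, 72.8% and 86.5% of their sequence windows with other genes. That Myl12b entry also has 100% of its exonic bases overlapped by Myl12a and the other Myl12b entry.

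Of 34 podocyte genes 1 rose and 3 fell on RT (7 and 4 when adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.387). Besides Wt1, Clic5 (a chloride channel protein of foot processes) fell, with a log2 fold change of -0.47 ± 0.09 (SE), from 23.7 ± 3.11 CPM (SD, n = 5) to 17.2 ± 1.56 CPM (SD, n = 6, adjusted p = 0.00167). Pdpn had -0.13 ± 0.03 (SE, adjusted p = 0.0309) and Ptgds (a prostaglandin D synthase) 1.04 ± 0.29 (SE, adjusted p = 0.0315), and each call was lost when any of 6 single libraries was left out. Nphs1 (0.23, adjusted p = 0.491), Synpo (-0.04, adjusted p = 0.663) and Podxl (0.13, adjusted p = 0.119) did not pass, though Podxl did without NT 2 (adjusted p = 0.0468) and with no filter beyond 1 count.

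Of the SRF and MRTF targets 11 of 26 rose and 1 fell (15 and 1 when adjusted over the list alone), with camera adjusted p = 1.33e-11, and 0.0122 with an estimated correlation. Srf itself (serum response factor) rose by 0.23 ± 0.04 on the log2 scale (SE, adjusted p = 0.00168) and Filip1l (a filamin-interacting protein) by 0.23 ± 0.04 (SE, adjusted p = 0.000329). Actin and actomyosin genes had 10 of 50 up and 0 down (17 and 2 when adjusted over the list alone, camera adjusted p = 4.09e-06). Actb (beta-actin) rose by 0.17 ± 0.04 (SE, adjusted p = 0.00688) and Flnc by 0.23 ± 0.04 (SE, adjusted p = 0.000160). YAP and TAZ targets had 7 of 24 up and 0 down (7 and 1 when adjusted over the list alone, camera adjusted p = 4.13e-06). F3 (tissue factor) rose by 0.37 ± 0.05 (SE, adjusted p = 8.85e-06) and Tgfb2 by 0.35 ± 0.05 (SE, adjusted p = 3.18e-05). Glomerular basement membrane genes had 6 of 21 up and 1 down (15 and 1 when adjusted over the list alone, camera adjusted p = 2.94e-12). Hspg2 rose by 0.24 ± 0.05 (SE, adjusted p = 0.00190), and Lamb2 (the laminin beta chain of the mature membrane) fell, at -0.17 ± 0.03 (SE), from 700 ± 25.8 CPM (SD, n = 5) to 623 ± 8.13 CPM (SD, n = 6, adjusted p = 0.00182). Fibrillar matrix genes had 11 of 34 up and 0 down (13 and 2 when adjusted over the list alone, camera adjusted p = 1.01e-09), with Serpinh1 (a collagen chaperone) up by 0.21 ± 0.04 (SE, adjusted p = 0.000492). Microtubules and cell processes had 3 of 28 up and 0 down (6 and 0 when adjusted over the list alone, camera adjusted p = 0.000846). With an estimated correlation the actin, YAP and TAZ, basement membrane, fibrillar matrix and microtubule lists each had an adjusted p of 0.0484, just under the threshold. Focal adhesion genes had 4 of 37 up and 1 down (7 and 2 when adjusted over the list alone, camera adjusted p = 0.0432, and adjusted p = 0.260 with an estimated correlation). Itga5, the fibronectin receptor chain, rose by 0.25 ± 0.04 (SE, adjusted p = 9.43e-05). That list call was lost when any of 6 single libraries was left out. Of 7 mesangial, pericyte and smooth muscle markers Acta2 rose, by 0.48 ± 0.10 (SE, adjusted p = 0.0121; 2 rose when adjusted over the list alone). The camera test gave an adjusted p of 0.0203, with an adjusted p of 0.0703 under an estimated correlation. The call of that list ended without RT 3 (adjusted p = 0.0535).

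Immediate early genes had 9 of 27 up and 0 down on RT (11 and 0 when adjusted over the list alone). By camera the list had an adjusted p of 8.30e-12, and an adjusted p of 0.0520 with an estimated correlation. Dusp6 rose by 0.88 ± 0.10 on the log2 scale (SE, adjusted p = 5.88e-05), Atf3 by 0.67 ± 0.11 (SE, adjusted p = 0.000196) and Ier5 by 0.34 ± 0.05 (SE, adjusted p = 1.13e-05). With the libraries numbered 1 to 5 the camera adjusted p was 1.90e-10. Cell division genes had positive fold changes in 34 of 34, and 2 rose (4 when adjusted over the list alone, camera adjusted p = 5.78e-08, and adjusted p = 0.270 with an estimated correlation), among them Cenpe, a kinetochore kinesin, by 0.34 ± 0.07 (SE, adjusted p = 0.00216). DNA replication genes had 2 of 38 up and 1 down (4 and 1 when adjusted over the list alone, camera adjusted p = 0.0429, and adjusted p = 0.548 with an estimated correlation), and the list call was lost when any of 6 single libraries was left out. Uhrf1 rose by 0.29 ± 0.07 (SE, adjusted p = 0.0121) and Dut, which clears dUTP, fell, at -0.16 ± 0.04 (SE, adjusted p = 0.0139), though not with thinned counts (adjusted p = 0.0537), a setting chosen after seeing the data.

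Interferon-response genes were lower on RT, with negative fold changes in 33 of 35 and a median of -0.25 on the log2 scale. Of these 6 fell and 0 rose by edgeR (20 and 1 when adjusted over the list alone), 13 fell and 1 rose by DESeq2, and 8 fell by limma voom. Camera gave an adjusted p of 2.25e-11, and an adjusted p of 0.183 with an estimated correlation. Zbp1 had a log2 fold change of -0.71 ± 0.16 (SE, adjusted p = 0.00595) and Parp14 (an ADP-ribosyltransferase) -0.23 ± 0.05 (SE, adjusted p = 0.00365). Of 6 immune markers Csf1r (the macrophage colony-stimulating factor receptor) rose and the antigen presentation genes H2-Aa and Cd74 fell (1 and 3 when adjusted over the list alone, camera adjusted p = 0.0429, and adjusted p = 0.183 with an estimated correlation). The list call, like that of Cd74, was lost when any of 9 single libraries was left out. Among the inflammatory cytokines and NF-kB targets 3 of 24 rose and 1 fell (6 and 1 when adjusted over the list alone, camera adjusted p = 0.215), the fall being C3 (complement component 3), at -0.43 ± 0.08 (SE, adjusted p = 0.00789).

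Mitochondrially encoded genes were lower in 11 of 12, with 2 past the threshold by edgeR (7 when adjusted over the list alone), 4 by DESeq2 and 5 by limma voom. As a list they had a camera adjusted p of 3.75e-07, and an adjusted p of 0.0657 with an estimated correlation. Cytosolic ribosomal protein genes were higher as a list with 0 of 79 past the threshold by edgeR and 4 by limma voom (camera adjusted p = 0.00199, and adjusted p = 0.593 with an estimated correlation). That call ended without NT 3, NT 4 or RT 5 (adjusted p = 0.161, 0.0563 and 0.137). Of 10 parietal epithelial markers 2 rose and 1 fell (3 and 2 when adjusted over the list alone, camera adjusted p = 0.358). Aldh1a2 (a retinoic acid synthase) rose by 0.21 ± 0.04 on the log2 scale (SE, adjusted p = 0.00100) and Cldn1 (claudin 1) fell, at -0.21 ± 0.05 (SE, adjusted p = 0.0157). In all, 21 of 31 lists passed, 18 up and 3 down, 6 of them with an estimated correlation, and 11 of the 21 passed in all fits with a single library left out. The RT and NT libraries stood apart, with 17.8% of the variation between the groups (exact permutation p = 0.00216, the smallest that 462 splits can give). The count of 603 genes was 365 without NT 3.

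**Figure D4:**
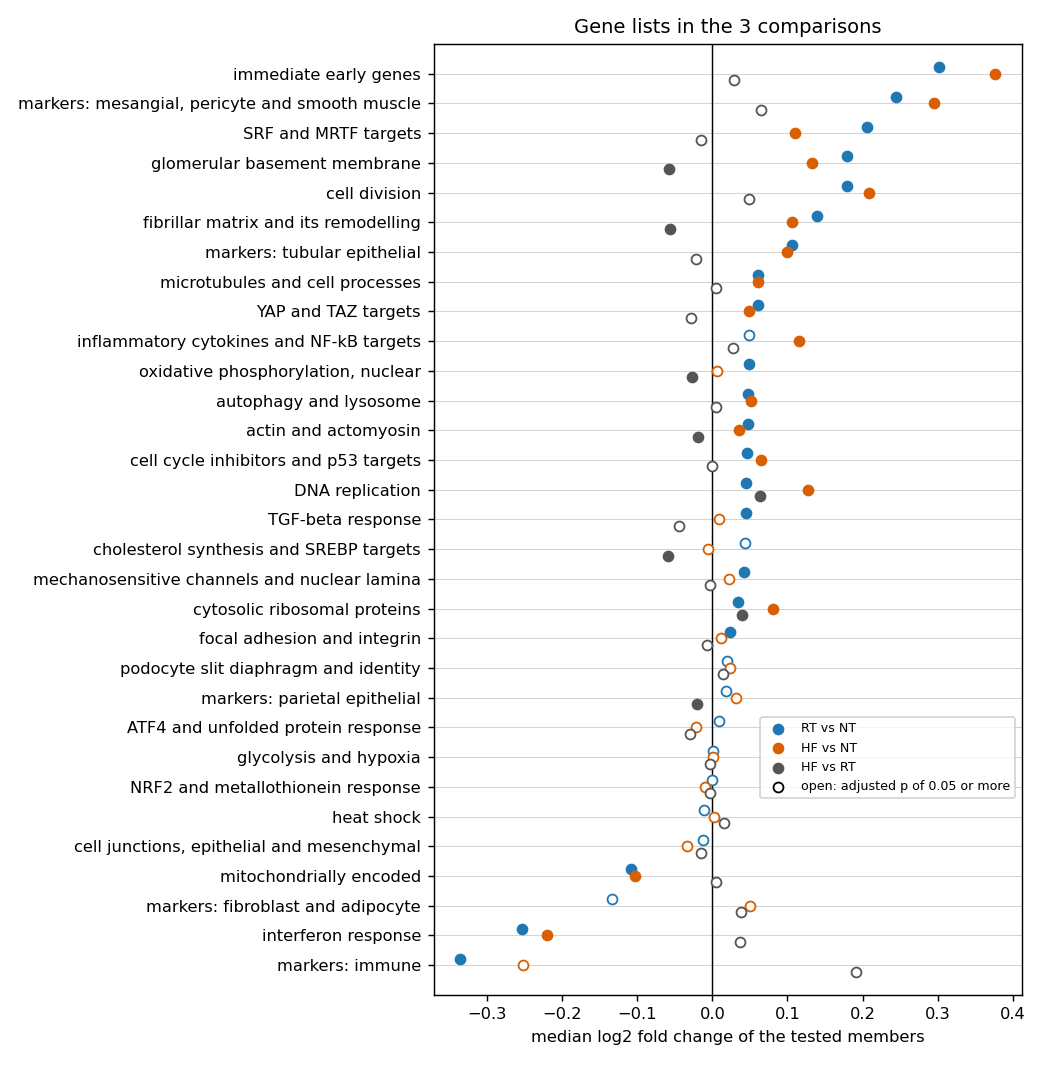
Median log2 fold change of the tested members of each list (x axis), 1 line per list (y axis) and 1 marker per comparison, filled where camera passed with the preset correlation. Immediate early genes have the largest positive medians against NT (0.38 for HF and 0.30 for RT) and interferon-response genes a median of -0.22 for HF and -0.25 for RT.

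The changes on the 2 topographies against NT overlapped in part. Of the 354 genes changed on HF and the 603 on RT, 205 were changed on both, all in the same direction (140 up, 65 down), against 5.76 and 1.82 for independent lists of these sizes. The log2 fold changes correlated across the 15196 genes (r = 0.71), where genes are not independent replicates. Simulated unchanged groups, with the same simulated NT libraries in both comparisons and genes drawn independently, gave a median r of 0.556. With the NT libraries divided between the comparisons, the median r over 20 ways was 0.177 (0.147 to 0.217) and the median number of shared genes 48 (26 to 63), or 23.9% of the genes called on HF. Of the 32 genes that differed between HF and RT, 18 had also changed on RT against NT, 7 on HF against NT and 8 on neither. These comparisons share the RT or the HF libraries, which alone favors such an overlap, and it was not corrected for.

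**Figure D5:**
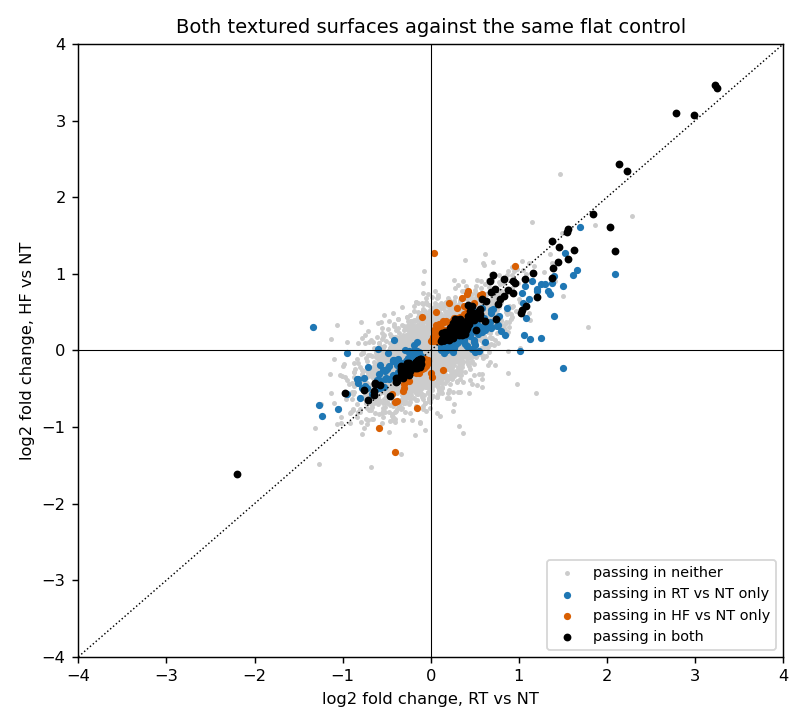
Log2 fold change of HF against NT (y axis) against that of RT against NT (x axis), 1 point per tested gene, colored by the comparison in which the gene passed. The 205 genes that passed in both lie on the same side of 0 in both, with r = 0.71 over all 15196 genes.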

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

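In this part, the tests of depth for RT against NT, of tubular cells and of handling shared by replicate number were chosen only after the result was seen. Among 288 groups of libraries tested for a library far from the rest, 13 had one, and chance alone gives about 1 in 20, or 14.4. They fell on 9 libraries, at most 2 on each.

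The count of 603 genes changed on RT against NT was the largest, and RT held the deepest libraries. Depth argues little: with every library thinned to the smallest total, 564 genes changed. GC content and gene length were corrected in each library for the 98.3% of tested genes with a value. On that set a limma test of log2 CPM, in place of edgeR, called 613 genes without the correction and 732 with it. Of the 613 genes, 539 were still called the same way. Of 100 splits, 1 gave as many genes for HF against NT (354, highest other 238). For RT against NT it was also 1 of 100 (603, highest other 94), in both cases the real split alone. These counts argue against chance at 0.05 for both, as far as libraries can be exchanged freely between groups. For HF against RT, 2 of 100 gave as many (32, highest other 79), under the 0.05 set in advance. The other split there, with RT 5 and HF 3 exchanged, gave more genes than the real one. The real grouping without HF 3 gave 89. The HF and RT libraries did not separate as a whole (exact permutation p = 0.0541), so chance is not excluded for that comparison. A response to topography is one hypothesis and stays open beside an unrecorded difference in how the RT and NT cultures were handled.

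Some of the largest rises on both topographies against NT were genes known from kidney tubules, such as Slc6a18, Havcr1 and Cyp2j5. As a theme this was not tested, and of the 8 tubular markers fixed in advance 0 passed on HF and 2 on RT. Slc6a18, Havcr1, Kif12, Msln and Cckar lay above the highest NT library in all 6 RT and all 6 HF libraries, and Cyp2j5 in 6 RT and 5 HF libraries. Carried-over tubular cells were tested by the 12 of 18 tubule markers in the table that were under 1 CPM on NT. The highest of these on RT, Hnf4a, reached 0.823 CPM where Slc6a18 reached 7.07 CPM. Slc34a1, abundant in proximal tubules, had no count in any library. This argues against carried-over cells that express these markers. Tubular cells without them would not be seen, and markers already abundant on NT, such as Cdh16 and Lrp2, were outside the test. Reads shared with related genes are argued against for Slc6a18, Havcr1, Cyp2j5 and Kif12, of which at most 0.515% of the sequence windows occur in another gene. Induction of these genes within E11 cells may be the source, as a hypothesis found and tested on the same data, and a change in the mixture of cells within the line was not tested.

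Immediate early genes differed by replicate number across the 3 groups. Fos was lowest in number 1 of each group (5.68 CPM in NT, 8.44 in RT and 9.48 in HF), against up to 20.4 in NT, 27.4 in RT and 31.2 in HF. Numbers took 93.6% of the within-group variance of the list, where chance gives 35.7% (permutation p = 0.000520), and it was the 1 of 31 lists that passed after adjustment. Depth is argued against, since thinned counts gave 92.4% (permutation p = 0.000710). Handling shared by number, such as the order of lysis, could account for it and remains open, and no biological explanation was tested because the labels give none for the numbers.

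Single libraries far from the rest of their group were these. In HF 5 the 10 largest genes held 4.67% of the counts, against 4.40 to 4.47% in the other HF libraries. Col8a1 was highest in RT 6 at 223 CPM, and Actn3 too at 3.25 CPM, a gene that was higher on HF than on RT. Hspg2 was lowest in RT 5 at 996 CPM. In NT 4, Racgap1, a cytokinesis gene, was lowest at 21.4 CPM and Atp6v0e2, a proton pump subunit, highest at 6.47 CPM. Vcl (vinculin) was lowest in NT 5 at 234 CPM and Usp18 highest at 16.7 CPM. The gene mt-Nd6 was highest in NT 3 at 725 CPM, Atf3 highest in NT 2 at 10.2 CPM and Zbp1 highest in HF 1 at 5.90 CPM. The antigen presentation genes H2-Eb1 and Cd74 were lowest in NT 1, at 14.8 CPM against 29.0 to 32.8 and at 4.88 CPM against 11.9 to 13.7 in the other NT libraries.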

How the results depend on the processing

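In this part, the fits on libraries numbered 1 to 5, on thinned counts and with the estimated correlation and block together were chosen only after the result was seen. DESeq2 size factors, upper-quartile scaling, the stricter filter, no robust estimation and thinned counts kept the counts of changed genes within 1.5 times of 354, 32 and 603 (HF against NT, HF against RT, RT against NT). No filter beyond 1 count gave 597 and 148 for the first and second, DESeq2 556 and 89, limma voom 534 and 84, and only 2 groups in the fit 200 and 113. The replicate block gave 637, 125 and 995. With it Podxl passed for HF against RT and RT against NT, and Nes for HF against NT. Libraries with the same number correlated in their deviations from the group means by -0.0111 to 0.193 over 16 pairs, 2 of them over 0.1. The median was 0.0459, and correlations this weak do not settle whether same-numbered libraries were paired. The best match had the same number in 15 of 32 cases, against 5.67 by chance, a sign of a shared factor from the data and not from the design. PC2, with 11.6% of the variance, also tended to fall with the number in each group, though not at each step. It ran from 14.6 in NT 1 to -8.63 in NT 5, from 16.9 in RT 1 to -3.29 in RT 6 and from 2.56 in HF 1 to -7.49 in HF 6. The shared factor may thus reach beyond the immediate early genes. Libraries 1 to 5 gave 15 for HF against RT, with fewer samples. An added threshold of 1 on the log2 fold change left 23, 1 and 55, by construction. For the others the cause was not tested. Leaving out single libraries gave 202 to 604, 14 to 89 and 365 to 806 genes.

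Of 17, 8 and 21 lists that passed, 2, 0 and 6 did with an estimated correlation, which widens the spread allowed for lists whose members move together, 11, 0 and 14 with fry, and 2, 0 and 3 with the estimated correlation and block. The 3 for RT against NT were SRF and MRTF targets, basement membrane and immediate early genes, so the actin, YAP and TAZ, fibrillar matrix and microtubule calls ended there. Libraries 1 to 5 gave 4 for HF against RT, of which 3 were among the 8 and cell division (higher) was not, and the falls of the actin, matrix, cholesterol and oxidative phosphorylation lists were lost. Left-out libraries gave 4 to 8 lists for HF against RT. The separation of HF and RT was 10.6% (exact permutation p = 0.0541), 10.7% over all tested genes (exact permutation p = 0.0216), 10.8% over 500 genes (exact permutation p = 0.0801), 10.1% with a prior count of 0.5 (exact permutation p = 0.0866), and 10.8 to 12.1% with single libraries left out (exact permutation p up to 0.152). The overlap of 205 genes was 48 with the NT libraries divided. The difference in total counts of HF and NT ran from -0.0924 (without NT 2) to 0.840 M, and that of HF and RT in the share of the 10 largest genes from -0.0475 to 0.0259 percentage points, turning positive without RT 1 (0.0259), HF 2 (0.00657) or HF 6 (0.00657).

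Of the called genes that the naming rule took, 27 of 42, 8 of 18 and 44 of 51 kept their call with each library left out, and none changed sign. Depth limits the smallest changes and genes of few counts.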

Other observations

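The gene groups, single genes and the cell density relation in this part were chosen only after the result was seen, except that the prediction for cell density was written before its test. The groups are given as counts without a group test, since they were put together from genes already seen to change. Single-gene p-values were adjusted over all genes tested.

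Several complement genes were lower on RT. Of 16 tested complement components and regulators, 6 fell and 1 rose on RT against NT, 4 were higher and 0 lower on HF than on RT, and 1 rose and 0 fell on HF against NT. The first 2 of these comparisons share the RT libraries. A deviation of RT by chance would thus show in both with opposite signs, which bears on each gene here that was lowest on RT. C1ra, a protease of the classical pathway, had a log2 fold change of -0.25 on RT against NT (adjusted p = 0.000271) and 0.24 on HF against RT (adjusted p = 0.00124), and C1s1, the protease it activates, -0.24 (adjusted p = 0.00124) and 0.22 (adjusted p = 0.0180). Of their sequence windows 35.6% and 20% also occur in another gene, for C1ra in most part its paralog C1rb. Dio2, the deiodinase that activates thyroid hormone, was lowest on RT too, at 0.853 ± 0.258 CPM (SD, n = 6) against 2.17 ± 0.602 CPM on NT (SD, n = 5, log2 fold change -1.34, adjusted p = 0.00142) and 2.67 ± 0.818 CPM on HF (SD, n = 6, 1.64 for HF against RT, adjusted p = 0.000621). Edn1 (endothelin 1) was highest on HF, at 35.6 ± 2.36 CPM (SD, n = 6), with log2 fold changes of 0.34 against NT (adjusted p = 0.00377) and 0.28 against RT (adjusted p = 0.0482).

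Of 13 genes of ERK feedback, 2 rose on HF (Dusp6 and Etv5) and 2 on RT (Dusp6 and Spry1), and 13 and 11 had positive fold changes. Outside that group, Epha2, an ephrin receptor, rose by 0.23 on HF (adjusted p = 0.0113) and by 0.30 on RT (adjusted p = 0.000415), and Tgfa, a ligand of the EGF receptor, by 0.76 (adjusted p = 0.0327) and 0.68 (adjusted p = 0.0420). Of 8 genes of MHC class II, 2 fell on HF and 3 on RT. Of 16 Notch genes, 4 rose and 0 fell on RT against NT, 1 rose on HF against NT, and 2 (Jag1 and Hes1) were lower on HF than on RT.

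YAP and TAZ targets and cell division genes were both higher as lists on RT and HF with the preset correlation, and a difference in cell density could move both. With an estimated correlation, cell division passed on neither surface (adjusted p = 0.235 on HF and 0.270 on RT) and YAP and TAZ targets only on RT (0.125 on HF and 0.0484 on RT). If density varied among the libraries of a group and moved both lists, their scores would vary together there. Over the 17 libraries, as deviations from the group means, Pearson's r was 0.413 (permutation p = 0.186) and Spearman's rho 0.238 (permutation p = 0.441), and r was 0.123 without the 2 farthest libraries. This was the only relation of its kind computed. A density that differed only between surfaces would leave no such relation, so the test cannot address it. Density and topography cannot be told apart here, and cell counts or images of the cultures would decide it.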
